A study of Rattus norvegicus with 8 samples.

How the data were processed

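Total RNA of rat liver was labelled with Cy3 and hybridised to 1-colour Agilent arrays, per the labels' protocols, and 8 scanner files and a value table of the whole series were used. The deposited scanner files give the intensity of each spot (processed signal, mean signal and local background), made with Agilent Feature Extraction, per the file headers version 11.5.1.1 and per the submitters' processing notes version 10.7. The 8 arrays were on 1 slide and had 1 scan time, per the file headers, and control and STL arrays alternated in position. The authors' series table holds intensity on a linear scale: each of its 8 columns was the processed signal of 1 array times a constant that brought the 75th percentile to about 1000, with no centring. The medians of the columns lay between 42.1 and 48.9. In 6 of the 8 columns the values were those of another array of the same group than the column's label names, and in 0 columns those of the other group, so which rat is which within a group stays unsettled, while the groups do not. How that permutation arose is not given in the sources used here.

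Of 62976 spots per array, 58717 were not control spots and held 45598 probes. Spots flagged as non-uniform or as population outliers were left out, which left 32 probes without a value on some array, and no spot was saturated. The main values were log2 of the processed signal minus the 75th percentile of each array over non-control probes, and spots of 1 probe were averaged. A probe counted as well above background on an array when at least 0.5 of its spots were. Probes were named through RefSeq accessions of the GRCr8 assembly (23863 probes), symbols (5124) or synonyms (351), and 16260 kept the name in the files. No coordinates of that assembly were used, and probe positions are those of the files, whose headers name rn4. For each of the 35828 genes or names the brightest probe over all arrays stood for the gene, and genes well above background on at least 4 of 8 arrays were tested, 21675 in all.

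Before averaging replicates, all 28 pairs of arrays were compared by the SD of their differences over repeated spots. It was set against that of 2 spots of a probe within an array. Both SDs were estimated from the median absolute deviation, which gives little weight to a minority of spots that differ strongly. Control 1 and control 2, with a ratio of 1.06, were averaged to 1 sample. The labels count 4 rats per group, and whether the pair was 1 RNA hybridised repeatedly or 2 livers that happened to be near-identical was not settled. The design fixed before the data were examined had all 8 arrays as samples. The fit with 8 arrays was run and its counts were seen before the pair was noticed, and the ratio limit of 1.5 was set after the pair ratios were known. The basis of the averaging was the noise between spots and not the calls, and both counts are given.

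Groups were compared with limma 3.58.1 in R 4.3.3, lmFit and eBayes with an intensity trend, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The 38 gene lists, written before the data were examined, were tested with camera at an inter-gene correlation of 0.01, camera with an estimated correlation, and fry, for lists with at least 5 genes tested. Adjusted p-values of the lists are over the 38 lists, and counts adjusted over the list alone use the members' limma p-values. List scores were compared by an exact permutation test. Where a probe was not well above background on any array of a group, the fold is a bound: the mean of the brighter group against the mean of, per array, the higher of the lowest signal among probes well above background and the probe's own. Files were read with Python 3.11.15 and pandas 2.3.3, and plots drawn with matplotlib 3.10.9.

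The named genes followed a rule fixed before the data were examined. In each direction the rule took the symbols with adjusted p under 0.05 and groups that do not overlap, at most 12, and where fewer than 5 passed, the direction was filled to 8 by the smallest unadjusted p. For each list described, it took at most 4 members past the threshold, or else at most 2 with the smallest unadjusted p. Hdac4, Hdac6, Gstp1, Ggt1, Cdkn1a and Tert were named whatever their values. For 2 of the lists, 1 member that the rule took is not reported here.

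The fit was tested on simulated data with 200 of the 21675 genes changed in each of 5 repeats, with independent genes. It called 46.6% of genes with a true log2 difference of 1, 83.9% at 2 and 93.6% at 3, and 34 of 107375 unchanged genes. Lists shifted by 0.5 were called in 15 of 15 cases with the preset and 13 of 15 with the estimated correlation, and unshifted ones in 2 and 0 of 175. Changed genes were drawn at random, and each gene's observed SD was taken as its true SD. In the data, large differences could fall on genes with a wide spread. Gstp1 differed by -3.31, with SDs of 1.06 and 1.81, and was not called (limma adjusted p = 0.178). The percentages of genes called therefore hold for the simulated setting only. Correlated genes were not simulated, so this does not test lists of co-regulated genes.

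Alternatives were quantile and median scaling, normexp background correction with an offset of 50, no filter and a filter on all 8 arrays, slide row and slide column as blocks, no trend, array weights, the mean of a gene's probes, the series table, other thresholds, and leaving out each array. The 8 arrays counted separately, slide column as a block over these 8, the blocks fitted with control 1 in place of the averaged sample, and leaving out both arrays of that sample were added after the data had been examined.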

Results

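Liver RNA of male Wistar rats was measured on 1-colour Agilent rat arrays, 1 array per labelled rat. The 4 control rats had received maltodextrin by gavage at 3.0 g/kg body weight, and the 4 rats of the other group had received butyrate-containing structured lipids, called STL from here on, at 1.65 g/kg body weight per day, a dose with the same energy content. Chemical hepatocarcinogenesis by the resistant hepatocyte protocol, in which a carcinogen is followed by conditions that favour the outgrowth of initiated hepatocytes, was begun in both groups during the treatment, and livers were taken at 8 weeks. The question of the comparison was which transcripts differed in livers under hepatocarcinogenesis when the structured lipids were given. The 75th percentile of the processed signal lay between 304 (STL 7) and 605 (control 4), and between 54.2% and 62.8% of probes were well above background on an array. The number of arrays limits the precision of every value.

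The arrays of control 1 and control 2 differed by less than any other pair. Over spots of probes printed repeatedly, the SD of their log2 differences, estimated from the median absolute deviation, was 0.0791. It was 0.0749 between 2 spots of a probe within an array, a ratio of 1.06. In the other 27 pairs of arrays this ratio was between 2.13 and 7.72. The lowest of these were those of control 1 and control 2 with STL 6, at 2.13 and 2.33, and the lowest other pair within a group, STL 6 with STL 8, was at 2.98. Over all spots well above background on every array, the SD estimated alike was 0.109 for control 1 and control 2. In the other pairs it was between 0.227 and 0.594. Over repeated probes, control 1 and control 2 therefore differed by about the noise between spots. They were averaged and counted as 1 sample, so that the comparison below is of 3 control samples against 4 STL samples.

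Cish, which encodes an inhibitor of cytokine receptor and STAT5 signalling, rose in the STL livers. Its normalised log2 signal was -1.34 ± 0.16 (SD, n = 3) in the controls and 0.85 ± 0.23 (SD, n = 4) in the STL livers, a difference of 2.19 (SE 0.15, 95% interval 1.84 to 2.54), or 4.56-fold, and it was higher in 4 of 4 STL livers than in any control. Its only probe, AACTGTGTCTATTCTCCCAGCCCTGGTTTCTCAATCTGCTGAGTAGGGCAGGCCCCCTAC, lies on chromosome 8 from 112545330 to 112545389 in the rn4 build that the file headers name, and was well above background on all 8 arrays. The adjusted p by limma with Benjamini-Hochberg adjustment over 21675 genes was 0.00576. Cish was the only gene past the threshold of 0.05, with 1 gene higher and 0 lower, while 4106 genes had an unadjusted p under 0.05 by limma, 2497 higher and 1609 lower in STL. Another split of the same 7 samples, STL 5, 7 and 8 against the rest, which differs from the real split only in STL 6, gave 4328 such genes. With median scaling 1629 of 3575 such genes were higher. Of the 4106 genes, 670 differed by at least 2-fold, 248 higher and 422 lower. With each of the 8 arrays counted as a sample the count past the threshold was 21 genes, 13 higher and 8 lower, and without STL 6 it was 46 genes. It was 3 genes without control 3 and 1565 with array weights. With slide column as a block and control 1's array alone for the averaged sample, which left STL 6 without a control in its column, it was 53 genes, 17 higher and 36 lower. With control 1 and 2 both left out it was 212 genes, 78 higher and 134 lower. Cish stayed past the threshold in each of these fits, but not with slide column as a block over all 8 arrays, where each column holds 1 control and 1 STL array (adjusted p = 0.0717). There the only gene past the threshold was Kcnn2, a potassium channel gene named after its values were seen, with a log2 difference of 2.44 (adjusted p = 0.0171), against 2.25 (adjusted p = 0.165) in the comparison of 3 against 4 samples.

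Next in order of p were genes that did not pass the threshold. Nr1d2, a repressor of the circadian clock, was 4.27 ± 0.38 (SD, n = 4) in STL against 2.66 ± 0.19 (SD, n = 3) in the controls, a log2 difference of 1.61 (limma adjusted p = 0.0982). Foxa2, a transcription factor of hepatocyte identity, was higher by 1.34 (adjusted p = 0.0982), and Tns2, which codes for a focal adhesion protein, by 0.91. Plaat1, a phospholipid-modifying enzyme, was higher by 1.38, the potassium channel gene Kcnh1 by 2.94, the immediate early transcription factor gene Csrnp1 by 1.28, and the neuronal RNA-binding protein gene Elavl2 by 2.23, with Elavl2 well above background on 1 of the 4 control arrays. In the other direction, the log2 difference was -1.57 for Nrg1, an epidermal growth factor family ligand, and -2.96 for Serpinb1a, a protease inhibitor (adjusted p = 0.0986 for both). It was -0.87 for Plin2, a coat protein of lipid droplets, and -1.17 for Tnfrsf12a, the receptor of TWEAK (adjusted p = 0.106 for both). It was -1.11 for the interferon-inducible GTPase gene Ifi47 and -2.69 for Sfnl1 (adjusted p = 0.111 for both). Dyrk3, a protein kinase gene, and Rnf138l1 were not well above background on any STL array, and their signal was at least 3.40-fold and at least 4.53-fold lower there (adjusted p = 0.111 and 0.106). For the named genes with several probes tested here, Nr1d2, Nrg1 and Sfnl1, all probes had the same direction.

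Genes of cell division and of preneoplastic liver lesions were lower as groups in the STL livers. Of 35 cell cycle genes tested, 34 were lower, with a mean log2 difference of -1.02 (camera adjusted p = 8.01e-16, adjusted p = 0.482 with an estimated correlation). No member passed over all genes, with 0 of 35, and 15 passed adjusted over the list alone, all of them lower. Ccnd1, cyclin D1, was 0.65 ± 0.49 (SD, n = 4) against 2.11 ± 0.35 (SD, n = 3), and Ccne2, cyclin E2, was -3.26 ± 0.40 against -2.02 ± 0.48, neither past the threshold over all genes (limma adjusted p = 0.162 and 0.1701). The other Ccnd1 probe differed by -1.03. All 20 of the 20 preneoplastic lesion markers tested were lower, by a mean log2 difference of -1.44 (camera adjusted p = 1.02e-09, adjusted p = 0.482 with an estimated correlation), and 10 passed adjusted over the list alone against 0 over all genes. In that list Anxa2, annexin A2, differed by -1.75 and Aldh3a1, an aldehyde dehydrogenase, by -3.78 (limma adjusted p = 0.165 for both, not past the threshold). The NRF2 target list, with antioxidant and pentose phosphate genes, was lower by a mean of -0.51, with 22 of 26 members lower (camera adjusted p = 3.97e-06, adjusted p = 0.482 with an estimated correlation) and 3 past the threshold adjusted over the list alone. Its leading members were Pgd, with -0.999, and the cystine transporter gene Slc7a11, with -3.60, neither past the threshold over all genes. The list of DNA repair genes was lower by a mean of -0.20 (camera adjusted p = 0.00862, adjusted p = 0.482 with an estimated correlation), with 0 members past the threshold adjusted over the list alone and the DNA ligase gene Lig1 at -0.53. The list did not pass without control 3 (adjusted p = 0.0584) or without control 4 (adjusted p = 0.0613).

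The control livers were not alike in these groups. The cell cycle score, the mean of the members' log2 signals centred over the 7 samples, was 1.08 in control 3 and 1.01 in control 4 but -0.35 in the averaged control 1 and 2, which lay within the STL range of -0.63 to -0.22. The preneoplastic lesion score was 1.61 in control 4, 0.57 in control 3 and 0.29 in the averaged sample, while STL 6, at 0.36, lay above the averaged control and the other STL livers lay between -1.22 and -0.69. The exact two-sided permutation p for these scores was 0.114 for each, and 3 samples against 4 cannot give less than 0.0571.

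**Figure D1:**
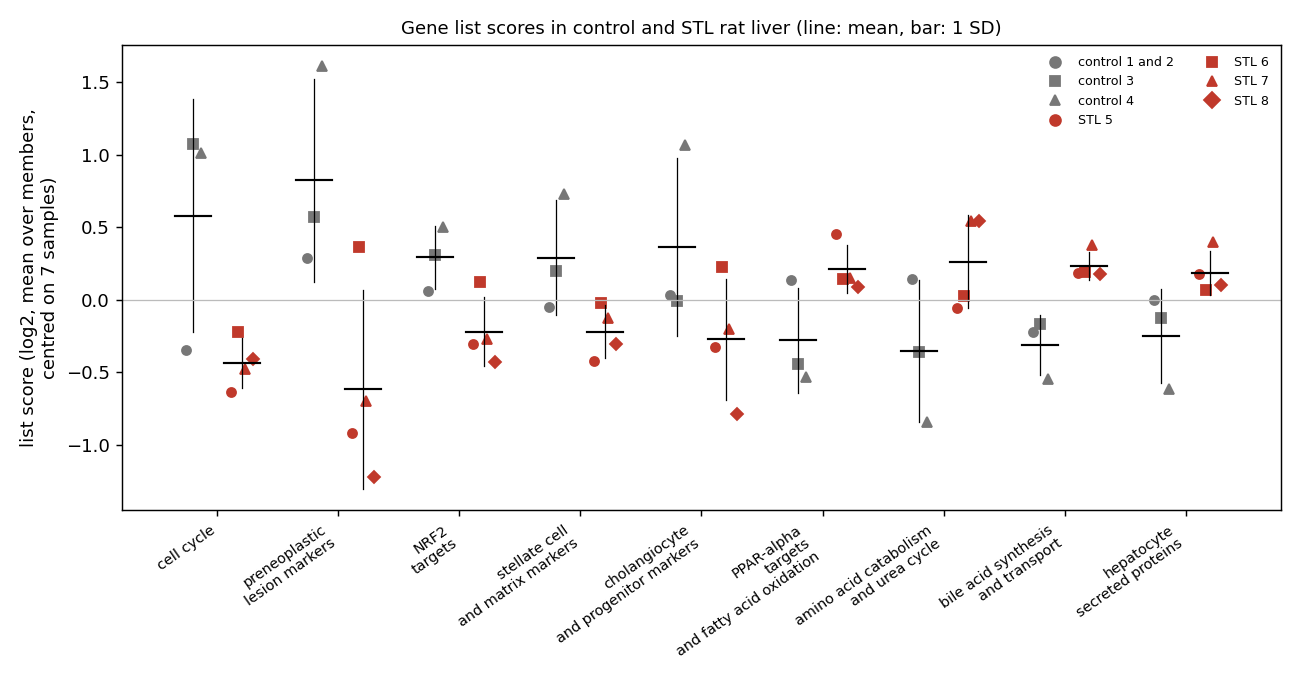
Scores of 9 gene lists in the 7 samples, in log2 units on the vertical axis, with 1 point per sample, grey for control and red for STL, the mean as a horizontal line and 1 SD as a vertical line. The cell cycle score of the averaged control 1 and 2, -0.35, sits among the STL livers while controls 3 and 4 sit at 1.08 and 1.01.

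Markers of stellate cells, of cholangiocytes and of some immune cells were also lower as groups, while lymphocyte markers were not. Of 20 lymphocyte markers 15 were higher, with a mean log2 difference of 0.24, and the list did not pass (camera adjusted p = 0.192). Its mean was 0.15 without control 4 and 0.12 with normexp. Stellate cell and matrix genes had a mean log2 difference of -0.51, with 20 of 24 lower and 7 past the threshold adjusted over the list alone (camera adjusted p = 7.27e-07, adjusted p = 0.482 with an estimated correlation). The collagen genes Col1a2 and Col3a1 differed by -0.90 and -0.75 and did not pass over all genes, and without control 4 the list mean was -0.29. Cholangiocyte and progenitor markers had a mean of -0.64, with 12 of 16 lower and 0 past the threshold adjusted over the list alone (camera adjusted p = 0.00136, adjusted p = 0.482 with an estimated correlation). The mean was -0.28 without control 4 and -0.40 with normexp. The keratin gene Krt19 was at -1.48 and the mucin gene Muc1 at -1.44. The interferon response list was lower by a mean of -0.30 (camera adjusted p = 0.000638, adjusted p = 0.482 with an estimated correlation), with 2 of 25 past the threshold adjusted over the list alone, and the mean was -0.47 with array weights. The chemokine gene Cxcl10 was at -1.09 and Gbp2 at -0.67. The list of inflammatory cytokines and NF-kB targets was lower by a mean of -0.30 (camera adjusted p = 0.00622, adjusted p = 0.482 with an estimated correlation). Adjusted over the list alone 3 members passed, 1 higher and 2 lower, and with no filter on dim probes the mean was -0.19. Its leading members went both ways and did not pass over all genes, Cxcl2 with -2.08, well above background on 2 of the 4 STL arrays, and Ptgs2, cyclooxygenase 2, with 1.098, and the other Ptgs2 probe had a log2 difference of -1.11. Ptgs2 passed adjusted over the list alone and was at -0.00742 with the mean of its probes. Macrophage markers were lower by a mean of -0.19 (camera adjusted p = 0.0148, adjusted p = 0.4998 with an estimated correlation), and by -0.12 without control 4. Gpnmb was at -1.30 and C1qc at -0.37. Granulocyte and mast cell markers were lower by a mean of -0.67 (camera adjusted p = 0.0306, adjusted p = 0.482 with an estimated correlation), and by -0.34 with normexp. The mast cell gene Mcpt1, whose probe the files name Mcpt2, was at -2.22. Cpa3 was at -2.35 and was well above background on 1 of the 4 STL arrays. None of Gpnmb, C1qc, Mcpt1 and Cpa3 passed over all genes. Adjusted over the list alone 0 macrophage markers and 3 granulocyte and mast cell markers passed, 1 of the latter higher and 2 lower. The stellate score was 0.73 in control 4 against -0.05 in the averaged control 1 and 2, and the cholangiocyte score was 1.07 against 0.03. Without control 4, 7 of the 18 lists that passed lost the call, the cholangiocyte (adjusted p = 0.0854), inflammatory (0.0613), macrophage (0.0613) and granulocyte and mast cell lists (0.109) among them. The macrophage list lost it in 4 of 22 alternatives, the others being slide column as a block with control 1's array (0.107), without STL 6 (0.0969) and without STL 8 (0.0565). The granulocyte and mast cell list lost it in 8 of 22, with adjusted p between 0.0529 and 0.239, also with quantile normalization, normexp, a filter on all 8 arrays, that block, array weights, without STL 5 and without STL 6.

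Cholesterol synthesis genes were lower and several hepatocyte programs were higher in the STL livers. The list of cholesterol synthesis and SREBP2 targets had a mean log2 difference of -0.37, with 21 of 27 lower and 0 past the threshold adjusted over the list alone (camera adjusted p = 5.23e-05, adjusted p = 0.482 with an estimated correlation). Fdps, farnesyl diphosphate synthase, was at -1.19 and did not pass over all genes. The list mean was -0.16 without control 3 (camera adjusted p = 0.0250) and -0.64 with array weights. Its score was 0.64 in control 3, while the averaged control 1 and 2, at -0.13, lay inside the STL range of -0.32 to 0.02. PPAR-alpha targets and fatty acid oxidation genes were higher by a mean of 0.49, with 32 of 37 higher and 12 past the threshold adjusted over the list alone, 11 of them higher (camera adjusted p = 4.91e-06, adjusted p = 0.482 with an estimated correlation). Ppara, the receptor itself, was 4.35 ± 0.24 (SD, n = 4) against 3.58 ± 0.21 (SD, n = 3), a difference of 0.77 (limma adjusted p = 0.165), and over its 3 probes the differences lay between 0.15 and 0.77, while Plin2, also in this list, was lower. Of 27 amino acid catabolism and urea cycle genes 26 were higher, by a mean of 0.62 (camera adjusted p = 6.50e-06, adjusted p = 0.482 with an estimated correlation), and by 0.37 without control 4. With all samples 1 member passed adjusted over the list alone. Tyrosine aminotransferase, Tat, was at 1.44 and the alanine aminotransferase gene Gpt2 at 1.54, neither past the threshold over all genes. The other probe differed by 1.02 for Tat and by 0.16 for Gpt2. The averaged control 1 and 2 lay inside the STL range in the PPAR-alpha and amino acid scores, at 0.13 and 0.14, while control 4 was at -0.53 and -0.84.

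Bile acid genes were higher in 18 of 19 members, by a mean of 0.54, with 5 past the threshold adjusted over the list alone (camera adjusted p = 0.000638, adjusted p = 0.482 with an estimated correlation). The sterol exporter genes Abcg5 and Abcg8 were higher by 0.79 and 0.84, not past the threshold over all genes. Phase I drug metabolism was higher by a mean of 0.58 (camera adjusted p = 0.000638, adjusted p = 0.482 with an estimated correlation), with 0 members past the threshold adjusted over the list alone. Cyp2e1 was at 0.92 and Fmo1 at 0.68. Without control 4 the phase I mean was 0.27 (camera adjusted p = 0.0208). Its score was -0.94 in control 4, while the averaged control 1 and 2, at 0.14, lay inside the STL range of -0.02 to 0.49. All 21 of the 21 hepatocyte secreted protein genes were higher, by a mean of 0.43 (camera adjusted p = 5.23e-05, adjusted p = 0.482 with an estimated correlation), and by 0.25 without control 4. With all samples 2 members passed adjusted over the list alone. Foxa2 is given above, and Cebpa, a hepatocyte transcription factor, was at 0.83 by 1 probe and 0.49 by the other. Periportal hepatocyte markers were higher by a mean of 0.57 (camera adjusted p = 0.0222, adjusted p = 0.482 with an estimated correlation), and by 0.33 without control 4. Serine dehydratase, Sds, was at 1.80 and Cdh1 at 0.48. Of 13 periportal members 3 passed adjusted over the list alone, 2 higher and 1 lower. Heat shock genes were higher by a mean of 0.25 (camera adjusted p = 0.0290, adjusted p = 0.4998 with an estimated correlation), although Cryab was at -1.50 and Hspb1 at 1.30. In that list 3 members passed adjusted over the list alone, 2 higher and 1 lower. Its mean was 0.15 without control 3, 0.15 with quantile normalization, 0.16 with normexp and 0.38 with control 1 and 2 both left out. In all, 18 of 38 lists passed camera with the preset correlation, 7 higher and 11 lower, and 0 passed with an estimated correlation or with fry's directional test, in which 0 and 4 lists had an unadjusted p under 0.05. By fry's test for changes in either direction, which does not compare a list with other genes, 11 lists passed. The cell cycle, preneoplastic lesion, stellate and NRF2 lists were not among them (adjusted p = 0.0781, 0.0926, 0.0781 and 0.0526 by that test). Some of the 11 were lists that camera did not call, and they are given below. The hepatocyte secreted list did not pass with quantile normalization (mean 0.16, adjusted p = 0.279) or normexp (mean 0.16, adjusted p = 0.254). The heat shock list lost the call in 7 of 22 alternatives, quantile normalization (0.112), normexp (0.115), the 8 arrays each counted as a sample (0.0769), these with slide column as a block (0.0850), without control 3 (0.147), without control 4 (0.0854) and without STL 7 (0.0906). The periportal list lost it in 5 of 22, slide column as a block with control 1's array (0.0657) and with all 8 arrays (0.0833), the 8 arrays counted without a block (0.0577), without control 4 (0.149) and without STL 6 (0.0647).

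Clock genes differed in both directions. Of 18 clock genes, 11 were higher and 7 lower, and the list did not pass camera as a whole (mean 0.41, adjusted p = 0.139). With median scaling camera's adjusted p was 0.0385 with the preset correlation and 0.503 with an estimated correlation. Over 22 alternatives the adjusted p with the preset lay between 0.0385 and 0.271. By fry's test for changes in either direction the list's adjusted p was 0.0343. Adjusted over the list alone, 7 members passed, 6 higher and 1 lower, against 0 over all genes. Nr1d1 was 0.94 ± 0.45 (SD, n = 4) in STL against -0.64 ± 0.47 (SD, n = 3), a log2 difference of 1.58 (limma adjusted p = 0.159), beside Nr1d2 given above. Cish and 11 clock genes, chosen for the plot after their values were seen, are drawn by sample. Clock genes left out of the plot include Ciart, at -0.21, Clock, at -0.02, Per1, at 0.16, and Hlf, at 0.73.

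**Figure D2:**
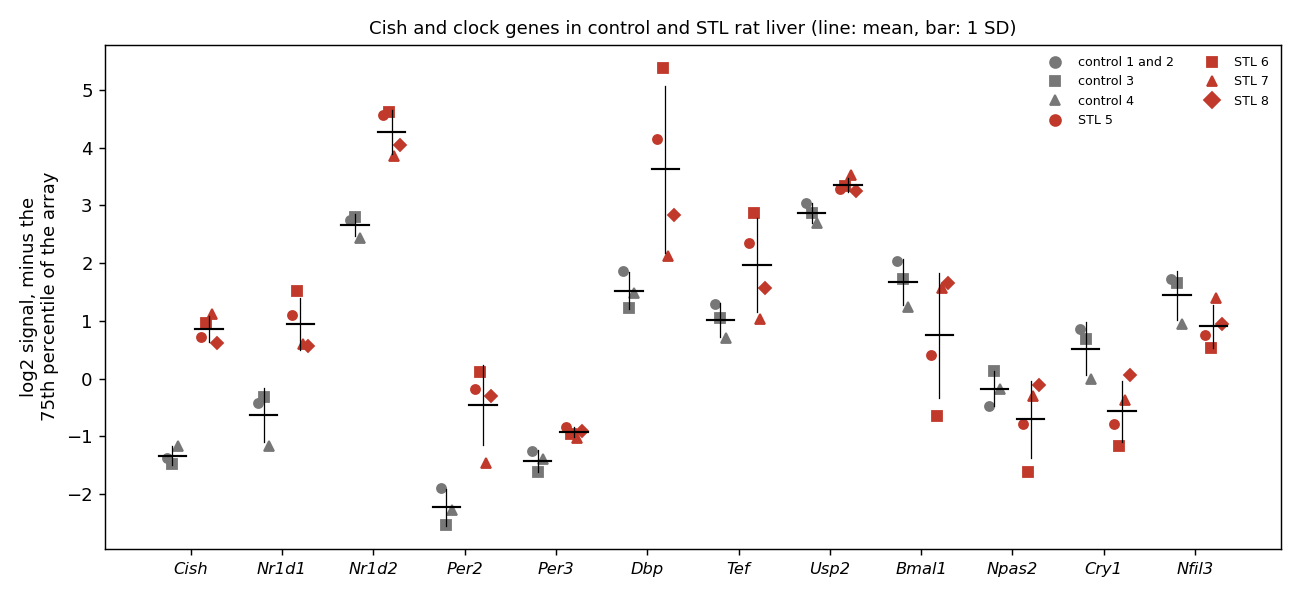
Log2 signal minus the 75th percentile of the array, on the vertical axis, for Cish and 11 clock genes in the 7 samples, with 1 point per sample, grey for control and red for STL, the mean as a horizontal line and 1 SD as a vertical line. Nr1d2 lay between 2.44 and 2.79 in the controls and between 3.86 and 4.62 in the STL livers.

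None of the 6 genes fixed in advance by name passed the threshold. Gstp1, the placental glutathione S-transferase that marks preneoplastic foci, was 2.72 ± 1.81 (SD, n = 4) in STL against 6.03 ± 1.06 (SD, n = 3), a log2 difference of -3.31 (SE 0.91, limma adjusted p = 0.178). Ggt1, another focus marker, differed by -2.20 (adjusted p = 0.207), and both genes' groups overlapped. Cdkn1a, the cell cycle inhibitor p21, differed by -0.54 (adjusted p = 0.304), and Tert, the telomerase catalytic subunit, by 0.61 (adjusted p = 0.210), where the other probe of each gene gave -1.30 and 0.29. The histone deacetylase genes Hdac4 and Hdac6 differed by -0.19 (95% interval -0.51 to 0.14, adjusted p = 0.478) and 0.29 (95% interval -0.05 to 0.64, adjusted p = 0.320), the other Hdac4 probe by -0.31, and the Hdac6 probe is named only in the description column of the files.

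The other 19 lists did not pass camera. Those with the lowest adjusted p were gluconeogenesis and glycogen (mean 0.31, adjusted p = 0.0865), apoptosis machinery (-0.09, 0.1397), the unfolded protein and amino acid stress response (0.11, 0.1397), adipose and mesothelial markers (-0.68, 0.155), telomerase and shelterin (-0.08, 0.183) and lymphocyte markers (0.24, 0.192). The adjusted p was 0.380 for both acute phase proteins (mean 0.14) and pancreatic acinar markers (mean -0.57), and 0.515 for sinusoidal endothelial markers (mean -0.10). The list of histone deacetylases, acetyltransferases and DNA methylation genes had a mean of 0.04 (adjusted p = 0.801), and the list of butyrate uptake, sensing and activation a mean of 0.05 (adjusted p = 0.817). For erythroid markers, p53 targets and pericentral and beta-catenin targets the means were 0.13, -0.02 and 0.12 (adjusted p = 0.833, 0.590 and 0.696). For fatty acid and triglyceride synthesis, glycolysis and carbohydrate response, immediate early genes, ketone body metabolism and phase II conjugation they were -0.08, -0.00337, 0.07, -0.02 and -0.12 (adjusted p = 0.559, 0.790, 0.790, 0.843 and 0.856). Mean, median and test differed in sign for the immediate early, butyrate, ketone body, phase II, glycolysis, pancreatic acinar and fatty acid synthesis lists. By fry's test for changes in either direction the histone deacetylase list passed (adjusted p = 0.0343). Its unadjusted p by fry's directional test was 0.0210 (adjusted p = 0.194). The unfolded protein, telomerase, adipose and p53 lists also passed the test in either direction (adjusted p = 0.0155, 0.0155, 0.0348 and 0.0462). The direction of the acute phase mean turned with quantile normalization, and that of the histone deacetylase list with median scaling. Each of these 19 means moved by over 1.5 times in at least 2 alternatives. The gluconeogenesis mean lay between 0.09, without control 4 (adjusted p = 0.366), and 0.47. The unfolded protein mean lay between 0.02 and 0.16. The adipose and mesothelial list, with 4 of 8 members higher and 4 lower, had a mean of -0.11 with the filter on all 8 arrays (adjusted p = 0.873) and -0.33 with normexp. Some lists passed in an alternative. These were gluconeogenesis without control 3 (adjusted p = 0.0282), without STL 8 (0.0315) and without control 1 and 2 (0.0391), the unfolded protein list without STL 8 (0.0315), apoptosis with no filter on dim probes (0.0144), fatty acid synthesis with array weights (0.0489) and acute phase proteins without control 1 and 2 (0.0258). With an estimated correlation the lowest adjusted p of any list in these alternatives was 0.252.

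With each probe tested on its own, 1 of 26978 probes passed by limma, that of Cish, with 1 higher and 0 lower, and 4919 had an unadjusted p under 0.05. The count was 30 with each of the 8 arrays counted as a sample, 54 without STL 6, 3 without control 3, 2 with slide column as a block over all 8 arrays, 39 with that block and control 1's array for the averaged sample, 224 with control 1 and 2 both left out and 1840 with array weights.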

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

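The scalings and left-out arrays used in this part were planned in advance, and the test of Socs2 and Bcl6 was written before their values had been looked at. The limits set on those alternatives, the splits of the samples and the tests of cell types and of the clock were chosen after the results were seen. Within the 4 STL livers, a sample stood far from the other 3 in 7 of 135 values examined, about the 6.8 that chance gives. The gap of that sample as a share of the group's range was 0.933 for Fdps, where STL 7 was at 3.52 against 3.01 to 3.04 in the others. It was 0.862 for Dgat2, where STL 8 was at 6.30 against 5.93 to 5.98. For Gpt and Gadd45a it was 0.899 and 0.850, with STL 6 at 4.66 and 2.23 against 5.29 to 5.36 and 1.66 to 1.75. For Hdac6 it was 0.880, with STL 5 at 0.34 against 0.64 to 0.68. It was 0.942 for the bile acid list score, with STL 7 at 0.38 against 0.18 to 0.19, and 0.830 for the PPAR-alpha list score, with STL 5 at 0.45 against 0.09 to 0.15.

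Other splits of the 7 samples into 3 and 4 gave counts as large as the real ones. For genes, 7 of the 35 splits gave at least the 1 gene of the real split, and the highest other split gave 50. For probes it was 6 of 35, with a highest other of 73, and for gene lists 2 of 35, with 18 in both the real and the highest other split. Camera at the preset correlation called at least 1 list in every other split. It called 17 with control 1 and 2, STL 5 and STL 7 against the rest, and 16 with control 1 and 2, STL 7 and STL 8. A small adjusted p by that test therefore does not by itself set the real grouping apart. Chance can therefore not be excluded for these counts. The split with 50 genes, against 1 in the real split, set STL 5, 7 and 8 against the 3 controls and STL 6. It differs from the real split only in the place of STL 6, so it keeps most of any difference between the groups. Its count points to a structure of the samples.

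The lower cell cycle and preneoplastic lesion lists were weighed first. The tables argue against array scaling as the cause, since the smallest share of either list's mean difference kept under quantile, median or normexp scaling was 0.761, with both calls kept by camera at the preset correlation. No single control among controls 3 and 4 carried it, since without either the smallest share kept was 0.726, again with both calls kept at the preset. For the cell cycle list, each of these fits kept the other of the 2 high controls, at 1.08 and 1.01. The averaged control 1 and 2, at -0.35, lay within the STL range, so that difference rests on controls 3 and 4 together. With an estimated correlation neither list passed, with adjusted p of 0.486 to 0.503 under the scalings and of 0.507 and 0.633 without control 3 and control 4. A larger hepatocyte share in the STL pieces would lower the markers of the other cell types alike. The lymphocyte score's difference exceeded the mean of the stellate, cholangiocyte and macrophage differences by 0.686 (95% interval -0.101 to 1.47, exact permutation p = 0.114). Sinusoidal endothelial markers, left out of that comparison, had a mean of -0.10, with 7 of 17 higher. With that interval the hepatocyte share stays open. Also open, and untested, are a different amount of lesion tissue in the pieces taken and an effect of the structured lipids.

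The clock genes were weighed against a difference in the time of day at collection, which the labels do not give. The mean of Usp2, Tef, Hlf, Ciart and Per3 minus the mean of Bmal1, Npas2 and Clock was higher in STL by 0.978 (95% interval -0.254 to 2.21, exact permutation p = 0.0571, the smallest that 3 against 4 can give). STL 5 and STL 6, at 3.16 and 3.59, stood apart from STL 7 and STL 8, at 2.05 and 2.04, which lay close to control 4, at 1.96. Within that score Ciart went the other way, at -0.21. Clock was well above background on 3 of 4 control and 2 of 4 STL arrays. The interval holds 0, and a shift from collection and one from the treatment cannot be told apart without collection times. An effect of the treatment on the clock remains an untested hypothesis.

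Cish is a target of STAT5, which growth hormone pulses activate in male rat liver, so a candidate explanation is a difference in pulse phase at collection. Socs2 minus Bcl6, which such a pulse would raise, differed by 0.916 (95% interval -1.02 to 2.85, exact permutation p = 0.229). Socs2 itself differed by -0.10 and the difference came from Bcl6, at -1.02, so the test leaves this open. Igf1 and Serpina3n, first planned for the same score and dropped because their p had been partly seen, differed by 0.23 and 0.24. Array scaling is argued against, since the smallest Cish difference over 4 scalings was 1.84 with adjusted p under the threshold in each. Of these, the series table is scaled by the 75th percentile like the main values, and normexp was followed by quantile normalization. With slide column as a block over all 8 arrays the adjusted p of Cish was 0.0717. An effect of the structured lipids on Cish stays open and untested.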

How the results depend on the processing

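The alternatives with 8 arrays counted, with slide column as a block over them, with control 1 and 2 both left out, and the stand-in of control 1 in the blocked fits were chosen after the data had been examined. Cish kept its direction in all 22 alternatives and its call in 21, with log2 differences of 1.84 to 2.28 and adjusted p of 0.000749 to 0.0717, the last with slide column as a block over 8 arrays. The count of genes, 1, was 53 with slide column as a block and control 1's array for the averaged sample, which left STL 6 without a control in its column, 1565 with array weights, 21 with the 8 arrays each counted as a sample, 212 with control 1 and 2 both left out and 13 at adjusted p under 0.1. The count of probes, 1, was 39, 1840, 30, 224 and 16 in the same order, and 2 with the block over 8 arrays. Array weights were highest for control 3 (3.19) and STL 8 (2.12) and lowest for control 4 (0.412). The cause of these changes was not tested. Leaving out 1 array gave between 1 and 46 genes, between 1 and 54 probes and between 11 and 19 lists, with 46 genes and 54 probes without STL 6, 3 genes and 3 probes without control 3, and 11 lists without control 4. The count of lists, 18, was 0 with an estimated correlation and 0 with fry's directional test. The camera tests differed in the correlation, but not only in it. The estimate for the apoptosis list was -0.0170, under the preset of 0.01. Its unadjusted camera p was still higher with the estimate, at 0.111 against 0.0797. How much of the change from 18 to 0 came from the correlation was not tested. Among the 18 lists the estimated correlation lay between 0.0367 (inflammatory) and 0.702 (amino acid), against the preset of 0.01. It was 0.636 for the cell cycle list and 0.596 for the preneoplastic lesion list. For fry's directional test the cause was not tested. Fry's test for changes in either direction called 11, but not the cell cycle or preneoplastic lesion list. Of the 18 lists that passed, 10 kept the call in all 22 alternatives of scaling, filter, block, weights and samples, and none turned. Among the unadjusted p under 0.05, 2497 of 4106 genes were higher with the 75th percentile, 2096 of 3997 with quantile normalization and 1629 of 3575 with median scaling. With the 75th percentile and a limit of 2-fold added, 248 of 670 were higher. The balance of directions therefore depends on the scaling and on the limit.

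Directions that turned belonged to lists that had not passed camera and to genes that had not passed over all genes, though Ptgs2 had passed over its list alone. For the lists the cause was not tested, and for the genes their own probes differed in direction. The mean of the acute phase list was -0.0887 with quantile normalization and -0.0779 with normexp; without 1 array it lay between -0.0277 and 0.185. The histone deacetylase list was at -0.00725 with median scaling. The p53 list was at 0.00208 with the filter on 8 arrays, 0.00735 with the slide column block and control 1's array, and 0.0158 with the series table. The glycolysis list was at 0.0315 with that block, 0.0335 with the series table and 0.0165 without control 1 and 2, and between -0.0592 and 0.0352 without 1 array. The ketone body list was at 0.00949 with array weights, 0.0204 with the series table and 0.0219 without control 1 and 2, and between -0.0464 and 0.0151 without 1 array. With array weights the immediate early list was at -0.0727 and the pericentral list at -0.0137. Without 1 array the immediate early list lay between -0.0340 and 0.189 and the fatty acid synthesis list between -0.177 and 0.0884. With the mean of a gene's probes Xiap was at -0.224 and Ptgs2 at -0.00742. By its brightest probe Xiap was at 0.51, but only 1 of its 5 probes was higher in STL, and the lowest was at -0.47. The Ptgs2 probes were at 1.098 and -1.11. Dim probes limit the folds of Dyrk3 and Rnf138l1 to bounds.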

Other observations

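Some genes of the lists stood out that the report did not describe, with the smallest p of their lists and none past the threshold over all genes. In the unfolded protein list, Ddit3, the stress transcription factor CHOP, was higher by 0.49 and Hspa5, the chaperone BiP, by 0.39. In the telomerase and shelterin list Gar1, a component of H/ACA ribonucleoproteins, was at -0.96, by its other probe at -0.46, and Tinf2, a shelterin subunit, at 0.50. In the butyrate list Acss1, which activates acetate, was at -0.83 and Acsm3, a medium-chain acyl-CoA synthetase, at 1.34. Among the epigenetic enzymes Tet3 was at 0.55 and Ezh2, the methyltransferase of PRC2, at -0.92. The limma adjusted p of these 8 genes lay between 0.165 and 0.192.

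The groups did not overlap for 3651 of the 21675 genes, 16.8%, where chance gives 5.71%, although genes are not independent of each other.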
